A study of Homo sapiens with 10 samples.

How the data were processed

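Histone acetylation was profiled by CUT&RUN in immortalized human astrocytes, a fetal astrocyte line immortalised with SV40 that carries a doxycycline-inducible IDH1-R132H. In CUT&RUN an antibody directs a protein A/G-linked nuclease to its target in permeabilised cells, and the released fragments are sequenced. Antibodies against H3K9ac, H3K27ac and H4K16ac were used on cells without doxycycline and after 2 days and 7 days of doxycycline at 1 µg/ml. A library made with the HRP-linked secondary antibody, from cells without doxycycline, was the negative control. The 10 samples therefore form 9 antibody libraries and 1 control library, with 1 library per mark and time. The antibody libraries each have an island list; the control enters through the control counts in those lists, and no file of its own was used here.

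Per the submitters' processing notes, the tools were cutadapt, FastQC, Bowtie2 2.3.5.1, Picard, SICER and deepTools, and the genome build was hg19. Their settings are not given in the sources used here, nor is the handling of duplicate reads. Each list was called by the authors on 1 library against the HRP control, and no libraries were pooled, per the file headers and labels. The deposited columns hold, for each island, a count of antibody reads and a count of HRP reads, both as whole numbers and not normalised. The deposited log2 fold is the authors' own value per island: the log2 ratio of the 2 counts less 1 constant per list. That constant varied within a list by at most 3.11e-15, and an HRP count of 0 entered as 0.25. The deposited score was a fixed multiple of the log2 fold, within 1.14e-13. The deposited p-value was the Poisson upper tail of the antibody count given the scaled HRP count, recomputed within a relative difference of 7.28e-12. The largest deposited FDR per list lay between 0.0491 and 0.0499. All island lengths were multiples of 200 bp.

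The constant in each list gives the library's size relative to the HRP library, and this was the scaling fixed before the data were examined. The same control served all lists: across 36 pairs of lists, all 11317 islands with equal coordinates had equal control counts. No island ended past the hg19 length of any of the 23 chromosomes used, whereas islands on 13 of them ended past the hg38 length. Coordinates are 1-based on hg19. Across the lists, 1 island outside chromosomes 1 to 22 and X was left out.

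Islands of a mark's 3 lists that touched were merged into regions, and the antibody reads of each library's islands were summed per region. The log2 ratio over the library without doxycycline was taken after division by relative library size, over regions with an island in both libraries. Such a sum depends on how much sequence was called, so reads per kb of island stand beside it. Reads per kb depend in turn on which stretches passed the caller, so neither measure is free of calling. Intervals for a ratio of 2 counts and for shares are exact Clopper-Pearson intervals at 95%, and those for medians are order-statistic intervals at 95%. They take reads, islands or regions as independent and cover no difference between libraries. PCR reads without molecular identifiers are not independent molecules, so even counting error may be understated. The summed reads in a list are not the library's depth, which is known here only relative to the HRP library. Overlap meant at least 1 bp, and the chance level came from 20 placements of the islands at random within their chromosomes (5 between marks). No spike-in is named in the labels, so a change of the overall acetylation level cannot be separated from library size. With 1 library per mark and time there are no replicates, no test between conditions was possible, and no p-value is given for any of them.

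Plans for promoters, gene lists and named genes were not carried out. The annotation at hand is on GRCh38.p14, and coordinates on different builds were not mixed. Regions were named by position instead, under the rule fixed for that case: the 5 largest rises and the 5 largest falls per mark and time among regions with an island in both libraries and at least 50 reads in either. The first 3 each way are named in the text and the range of all 5 is given. Correlations between marks, planned over promoters, were run over pairs of regions of the 2 marks that overlapped each other most. The widest islands, the Giemsa bands, the chromosome shares and the regions missing from a list were chosen after the data were seen. Giemsa bands are the light and dark stripes of stained chromosomes, and their hg19 positions came from the table in circlize 0.4.16. Chromosome lengths came from GenomeInfoDb 1.38.1. Each island was given to the band holding its midpoint, and bands with at least 1000 reads in all 3 lists were compared by their share of a list's reads.

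The code for regions and ratios was tested on simulated data: counts for the islands of each mark's list without doxycycline were drawn with 200 of them changed. With rises set at 2 on the log2 scale, the median recovered at H3K9ac was 2.02 for the 2-day comparison and 2.01 for the 7-day comparison over 88832 islands. It was 2.01 and 1.98 at H3K27ac over 52044 islands, and 2.00 and 2.02 at H4K16ac over 110234. With falls set at -2 the medians were -2.04 and -2.04, -1.99 and -2.02, and -2.06 and -1.90, in the same order of marks. The simulation kept the island edges fixed, so it did not test calling. Alternatives covered the FDR, the fold and the read minimum, the overlap rule, the scaling, region length, and reads per kb. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.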

Results

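Island lists of H3K9ac, H3K27ac and H4K16ac were compared between astrocytes without doxycycline and the same line after 2 days and 7 days of IDH1-R132H induction. IDH1-R132H is the cancer-associated form of isocitrate dehydrogenase 1 that makes 2-hydroxyglutarate, and the series asks how its expression alters these acetylation marks. H3K27ac and H3K9ac mark active promoters and enhancers, and H4K16ac is a more widespread mark of open chromatin. Each mark and time was measured in 1 library, so every value below describes a library and has no replicate error. No library came from cells given doxycycline without IDH1-R132H. Doxycycline itself and time in culture therefore cannot be told apart from IDH1-R132H.

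Library size relative to the HRP control was 3.05, 4.17 and 4.88 for H3K9ac without doxycycline, at 2 days and at 7 days. For H3K27ac it was 3.98, 3.15 and 1.49, and for H4K16ac 2.53, 3.08 and 7.88, in the same order of times. The order of depth over time was thus opposite in H3K27ac and H4K16ac. Islands held 5730072, 7889407 and 9545292 antibody reads for H3K9ac, 12887909, 9485719 and 4742296 for H3K27ac, and 4209773, 5387670 and 18664203 for H4K16ac. The smallest island of a list held between 11 and 33 reads.

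H4K16ac islands covered 276 Mb without doxycycline, 334 Mb at 2 days and 586 Mb at 7 days, while their number went from 110234 to 93001 and 86615. H3K27ac islands went the other way, from 306 Mb to 257 and 222 Mb in 52044, 59549 and 84641 islands. H3K9ac covered 314, 327 and 374 Mb in 88832, 108321 and 95536 islands. Within each mark the covered length followed library size. Median island length was 3000, 2400 and 3200 bp for H3K9ac, 4200, 3200 and 2000 bp for H3K27ac, and 2000, 3000 and 4800 bp for H4K16ac. Antibody reads per kb of island, divided by relative library size, were 5.99, 5.78 and 5.23 for H3K9ac, 10.6, 11.7 and 14.3 for H3K27ac, and 6.02, 5.23 and 4.04 for H4K16ac. Within each mark these values ran opposite to library size, so reads per kb are no more free of depth than covered length. The summed reads per unit of library size were 1.01 and 1.04 times those without doxycycline for H3K9ac at 2 and 7 days, 0.931 and 0.982 times for H3K27ac, and 1.05 and 1.42 times for H4K16ac.

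**Figure D1:**
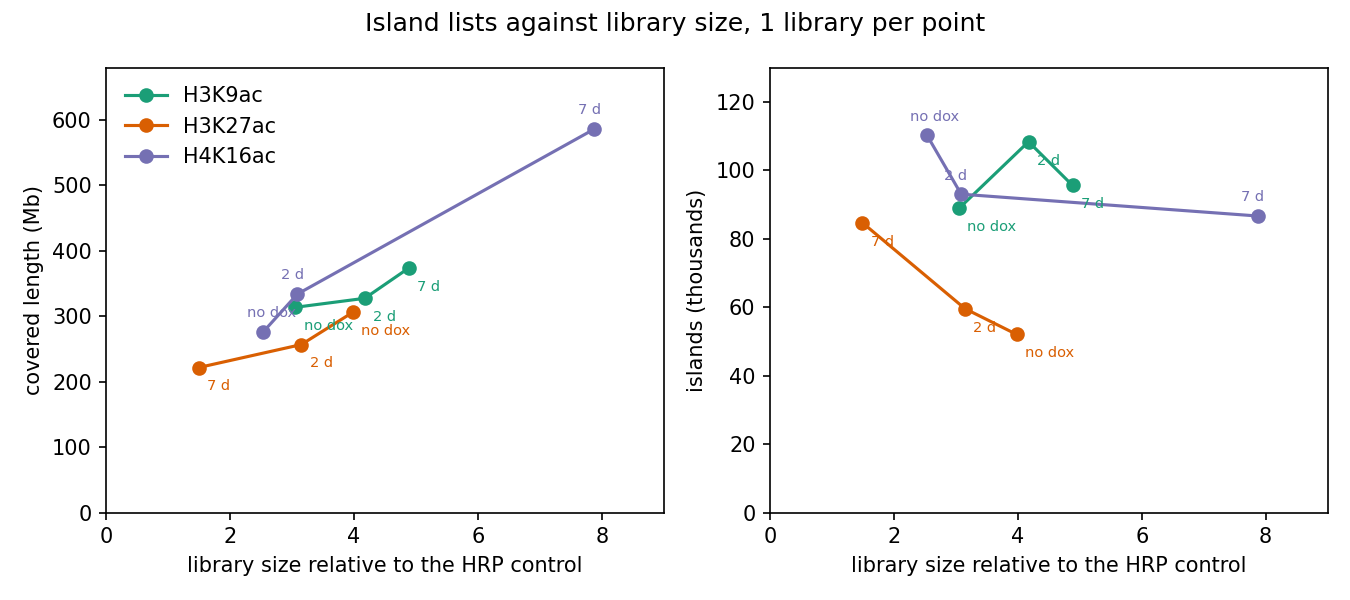
Covered length in Mb (left) and number of islands (right) against library size relative to the HRP control, with 1 point per library and a line joining the 3 times of a mark. Covered length rises with library size within each mark, to 586 Mb for H4K16ac at 7 days.

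The authors' fold of each island over the HRP control described how far islands stood above background within each list. Its median was 3.28 for H3K9ac without doxycycline (quartiles 2.11 and 6.12), 3.36 at 2 days (2.08 and 7.43) and 2.87 at 7 days (1.91 and 5.32). For H3K27ac the medians were 4.52 (2.68 and 7.91), 5.12 (2.94 and 10.0) and 6.93 (3.58 and 32.2). For H4K16ac they were 3.75 (2.24 and 9.73), 2.999 (1.99 and 5.67) and 2.18 (1.61 and 3.40). In H3K27ac and H4K16ac, though not in H3K9ac, these medians ran opposite to library size. Islands with no HRP read were 25.2% of the H3K27ac list at 7 days and 6.37% of the H4K16ac list at 7 days, and their fold rests on the value entered for 0.

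Most H3K27ac sites present without doxycycline were present during induction. Of 52044 islands, 88.0% (95% interval 87.7 to 88.3) overlapped an island at 2 days and 79.6% (79.3 to 79.9) at 7 days, and these held 97.1% and 94.3% of the reads. Random placement gave 17.7% and 20.0%. For H3K9ac the overlaps were 73.5% (73.3 to 73.8) and 74.0% (73.8 to 74.3), against 21.9% and 22.4% for random placement. For H4K16ac they were 55.9% (55.6 to 56.2) and 74.4% (74.1 to 74.7), against 18.8% and 26.9%. In the other direction, 86.7% of H3K27ac islands at 2 days and 64.5% at 7 days overlapped an island without doxycycline. The corresponding shares were 63.1% and 66.2% for H3K9ac, and 59.6% and 62.8% for H4K16ac. Taking the same number of islands from each list lowered the H3K27ac share at 7 days from 79.6% to 60.4%.

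Regions without an island at a later time were counted among those whose reads without doxycycline predicted at least 100 reads at the other library's size. Of 25251 such H3K27ac regions, 0.356% (0.287 to 0.438) had no island at 2 days, and of 13746 at 7 days 0.0655% (0.0299 to 0.124) had none. The shares for H3K9ac were 3.12% (2.90 to 3.34) of 23947 and 5.59% (5.33 to 5.87) of 29026. For H4K16ac they were 4.00% (3.65 to 4.37) of 11687 at 2 days and 17.3% (16.9 to 17.6) of 38869 at 7 days. The 7-day library was 3.11 times the size of that without doxycycline for H4K16ac, and 0.375 times for H3K27ac. The same cut thus took in regions with far fewer reads without doxycycline for H4K16ac, and these shares do not rank the marks. Most of the 6707 H4K16ac regions missing at 7 days, 6226, were thin ones with 100 to 200 expected reads, of which 27.7% were missing. The share was 3.91% at 200 to 500 expected reads and 0.0241% above. In the other direction, regions at 2 and 7 days with at least 100 reads expected without doxycycline lacked an island there in 1.499% and 2.07% for H3K9ac, 0.386% and 2.19% for H3K27ac, and 2.81% and 4.37% for H4K16ac. H4K16ac regions with the most reads but no island at 7 days lay at 5q14.1 (chromosome 5, 79373001 to 79382000, 166 reads without doxycycline) and 5q31.3 (chromosome 5, 142121401 to 142132600, 157 reads). The H4K16ac region at 4q28.1 (chromosome 4, 126255801 to 126287200) had no island without doxycycline, 322 reads at 2 days and 900 at 7 days. The H3K9ac region at 9q33.2 (chromosome 9, 125785201 to 125805200) likewise had no island without doxycycline, 249 reads at 2 days and 407 at 7 days. These 4 regions were picked after their values were seen, as the ones with the most reads or present at both times.

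H3K9ac ratios over the shared regions went both ways around a median slightly below 0. The median log2 ratio was -0.13 (-0.13 to -0.12) at 2 days over 53551 regions and -0.042 (-0.048 to -0.036) at 7 days over 52597, with quartiles of -0.54 and 0.25, and of -0.42 and 0.33. At 2 days 9.51% of regions were at least 2-fold lower and 4.64% at least 2-fold higher, and at 7 days 6.18% and 5.76%. Relative to the median these shares were 7.08% and 6.26% at 2 days, and 5.54% and 6.39% at 7 days. Per kb of island the medians were -0.032 and -0.17. At 2 days the 5 largest falls ranged from -3.13 to -3.003 and the 5 largest rises from 2.82 to 3.08. The largest fall was at 1q42.13 (chromosome 1, 229788201 to 229801200), with 141 reads over 13000 bp without doxycycline and 22 reads over 800 bp at 2 days, a log2 ratio of -3.13 (-3.85 to -2.48). Next were 10p13 (chromosome 10, 17034401 to 17042600) at -3.11 (-3.79 to -2.48) and 2q33.1 (chromosome 2, 198321801 to 198331400) at -3.10 (-3.99 to -2.31). The largest rise was at 2p13.1 (chromosome 2, 74422801 to 74434800), from 28 reads over 1600 bp to 325 over 12000 bp, a ratio of 3.08 (2.53 to 3.70). It was followed by 2p13.3 (chromosome 2, 69739601 to 69762800) at 2.998 (2.47 to 3.58) and 15q21.3 (chromosome 15, 58956401 to 58977200) at 2.93 (2.40 to 3.50). The 2p13.1 region was again among the 5 largest rises at 7 days, at 2.90 (2.34 to 3.51), with both ratios resting on the same 28 reads. The 5 regions that fell most at 2 days held 141, 151, 94, 120 and 164 reads without doxycycline. At 7 days they held 97, 0, 123, 129 and 226, in a library 1.60 times the size, where 0 means no island. At 7 days the largest falls were at 6p21.1 (chromosome 6, 42368601 to 42380000; -3.11, -3.65 to -2.61), 8p22 (chromosome 8, 17800401 to 17809400; -3.11, -3.77 to -2.50) and 3q26.32 (chromosome 3, 178098601 to 178113000; -3.04, -3.62 to -2.51). The largest rises were at 1p36.12 (chromosome 1, 21239801 to 21259600), 20q13.31 (chromosome 20, 55040201 to 55059400) and 3p21.31 (chromosome 3, 47930201 to 47948000), with ratios of 3.13 (2.60 to 3.72), 3.04 (2.54 to 3.59) and 3.01 (2.49 to 3.58). The 5 largest falls at 7 days ranged from -3.11 to -2.88 and the 5 largest rises from 2.90 to 3.13. Per kb of island the regions with the 5 largest changes each way at each time lay between -1.46 and 1.71. Of the 10 that fell in summed reads, 7 were higher per kb. Only stretches that passed the caller are counted, so a region that lost signal could keep only its densest part. The values per kb therefore cannot tell a change of signal from a change of called length.

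H3K27ac was slightly lower in summed reads and higher per kb of island, in libraries 0.791 and 0.375 times the size of that without doxycycline. The rise per kb cannot be told apart from the smaller library size. The median log2 ratio was -0.12 (-0.13 to -0.12) at 2 days over 42760 shared regions and -0.15 (-0.15 to -0.14) at 7 days over 38918, with quartiles of -0.36 and 0.078, and of -0.53 and 0.20. Per kb of island the medians were 0.14 and 0.46, as the median called length per region was 0.840 and 0.667 times that without doxycycline. Among island pairs of like length, overlapping by at least 80% both ways, the medians were -0.034 (12468 pairs) and 0.11 (5310 pairs). The largest fall at 2 days was at 6p21.1 (chromosome 6, 43069201 to 43078200), from 176 reads over 9000 bp to 23 over 800 bp, a ratio of -2.60 (-3.29 to -1.97). The next were 22q11.23 (chromosome 22, 24172201 to 24183600) at -2.50 (-3.20 to -1.87) and 14q24.2 (chromosome 14, 73785201 to 73798800) at -2.47 (-3.05 to -1.94). The largest rises at 2 days were at 1p36.13 (chromosome 1, 19461601 to 19476800; 2.02, 1.60 to 2.47), 6q25.3 (chromosome 6, 158357001 to 158366800; 1.94, 1.37 to 2.54) and 9q22.31 (chromosome 9, 95139601 to 95148800; 1.89, 1.46 to 2.34). At 7 days the largest fall was at 3p22.3 (chromosome 3, 33352601 to 33364800), from 379 reads over 11800 bp to 15 over 800 bp, a ratio of -3.24 (-4.09 to -2.50). It was followed by 4q13.3 (chromosome 4, 72070201 to 72080200) at -3.13 (-3.92 to -2.43) and 8p11.22 (chromosome 8, 38903201 to 38918000) at -3.002 (-3.93 to -2.20). The largest rise was at 6q26 (chromosome 6, 161722201 to 161726000), from 38 reads over 1400 bp to 80 over 3800 bp, a ratio of 2.49 (1.92 to 3.09) and of 1.05 per kb. Rises followed at 18p11.22 (chromosome 18, 9045801 to 9050000; 2.42, 1.80 to 3.06) and 17q25.1 (chromosome 17, 73207001 to 73217400; 2.26, 1.74 to 2.80). The 5 rises at 7 days, from 2.25 to 2.49, were also rises per kb, from 0.20 to 1.05, whereas all 5 falls at 2 days, from -2.60 to -2.43, were higher per kb. The 5 rises at 2 days, from 1.84 to 2.02, were higher per kb in 2 regions, and the 5 falls at 7 days, from -3.24 to -2.98, were higher per kb in 3.

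Wide H3K27ac islands were listed as several shorter ones during induction. Islands of 20 kb or more numbered 1323 without doxycycline, 603 at 2 days and 154 at 7 days, and 2680, 1728 and 869 after joining islands across gaps of at most 2 kb. The counts for H3K9ac were 92, 87 and 233, and for H4K16ac 18, 180 and 3417. Of the 1323 H3K27ac islands, 77.7% held 2 or more islands at 2 days and 95.7% at 7 days, none was empty, and the median share still covered was 87.3% and 70.8%. Wide islands were also split in libraries deeper than the one without doxycycline: 79.3% and 71.7% of the 92 in H3K9ac at 2 and 7 days, and 100% of the 18 in H4K16ac at 2 days, against 16.7% at 7 days. The widest, at 2p22.2 (chromosome 2, 36578001 to 36732400, 154.4 kb, 14903 reads), became 2 islands covering 99.5% of it at 2 days and 10 covering 93.0% at 7 days. The domain at 5p15.2 (chromosome 5, 14138201 to 14289200, 151.0 kb) became 4 and 13 islands covering 91.5% and 83.4%. Those at 17p11.2 (chromosome 17, 16921401 to 17040400), 7q32.3 (chromosome 7, 130550001 to 130657400) and 11q24.1 (chromosome 11, 121982801 to 122087600) held 16, 9 and 13 islands at 7 days. The log2 ratio of reads at 7 days was -0.28 at 2p22.2, -0.25 at 5p15.2, 0.21 at 17p11.2, -0.15 at 7q32.3 and -0.47 at 11q24.1, counting every island that touched the domain. The 7-day library had 0.375 times the size of the library without doxycycline.

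H4K16ac was higher in summed reads and lower per kb of island, in libraries 1.22 and 3.11 times the size of that without doxycycline. The fall per kb cannot be told apart from the larger library size. The median log2 ratio was 0.15 (0.14 to 0.16) at 2 days over 39969 shared regions and 0.42 (0.41 to 0.43) at 7 days over 47863, with quartiles of -0.38 and 0.69, and of -0.053 and 0.94. Per kb the medians were -0.20 and -0.58, and the median called length per region was 1.28 and 2.00 times that without doxycycline. Among island pairs of like length the medians were -0.098 (4597 pairs) and -0.34 (2885 pairs), and scaling by the reads in islands gave -0.089 at 7 days. The largest rise at both times was at 4q24 (chromosome 4, 107147201 to 107177600), from 19 reads over 1800 bp to 436 over 25200 bp at 2 days and 1020 over 30000 bp at 7 days. Its ratios were 4.24 (3.58 to 4.98) and 4.11 (3.46 to 4.85) in sums, and 0.43 and 0.050 per kb. At 2 days 20p12.1 (chromosome 20, 13512801 to 13542600; 3.87, 3.28 to 4.53) and 18q21.2 (chromosome 18, 52938001 to 52966400; 3.74, 3.10 to 4.45) followed. At 7 days 18q12.1 (chromosome 18, 26637801 to 26677400; 3.84, 3.26 to 4.49) and 9p22.3 (chromosome 9, 14603801 to 14633800; 3.82, 3.20 to 4.52) did. The 18q21.2 region was among the 5 largest rises at both times, as was 10p11.22 (chromosome 10, 32737401 to 32756800; 3.67 and 3.65). Both ratios of a region use the same count without doxycycline, 21 reads at 18q21.2 and 17 at 10p11.22. A low count there raises both, so the recurrence is not independent support. The largest falls at 2 days were at 1p36.22 (chromosome 1, 9648001 to 9676400; -3.36, -4.02 to -2.76), 1p36.12 (chromosome 1, 21641001 to 21662600; -3.35, -4.05 to -2.73) and 22q13.31 (chromosome 22, 44462201 to 44477600; -3.05, -3.72 to -2.44). At 7 days they were at 14q11.2 (chromosome 14, 23350401 to 23358200; -2.71, -3.17 to -2.26), 19q13.2 (chromosome 19, 38775201 to 38783200; -2.59, -3.02 to -2.16) and again 14q11.2 (chromosome 14, 23283801 to 23295400; -2.54, -2.97 to -2.11). These 3 were lower per kb too, at -0.50, -0.66 and -0.66, and the other 2 of the 5 largest falls, at 1q32.1 and 8q11.21, were higher per kb, at 0.062 and 0.78. The 5 falls ranged from -3.36 to -2.98 at 2 days, with 3 higher per kb, and from -2.71 to -2.39 at 7 days. The 5 regions that fell most at 2 days held 211, 193, 170, 163 and 194 reads without doxycycline. At 7 days they held 1060, 483, 201, 340 and 764, in a library 3.11 times the size. The 5 rises ranged from 3.49 to 4.24 at 2 days, with 2 higher per kb, and from 3.65 to 4.11 at 7 days, with 1 higher per kb.

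**Figure D2:**
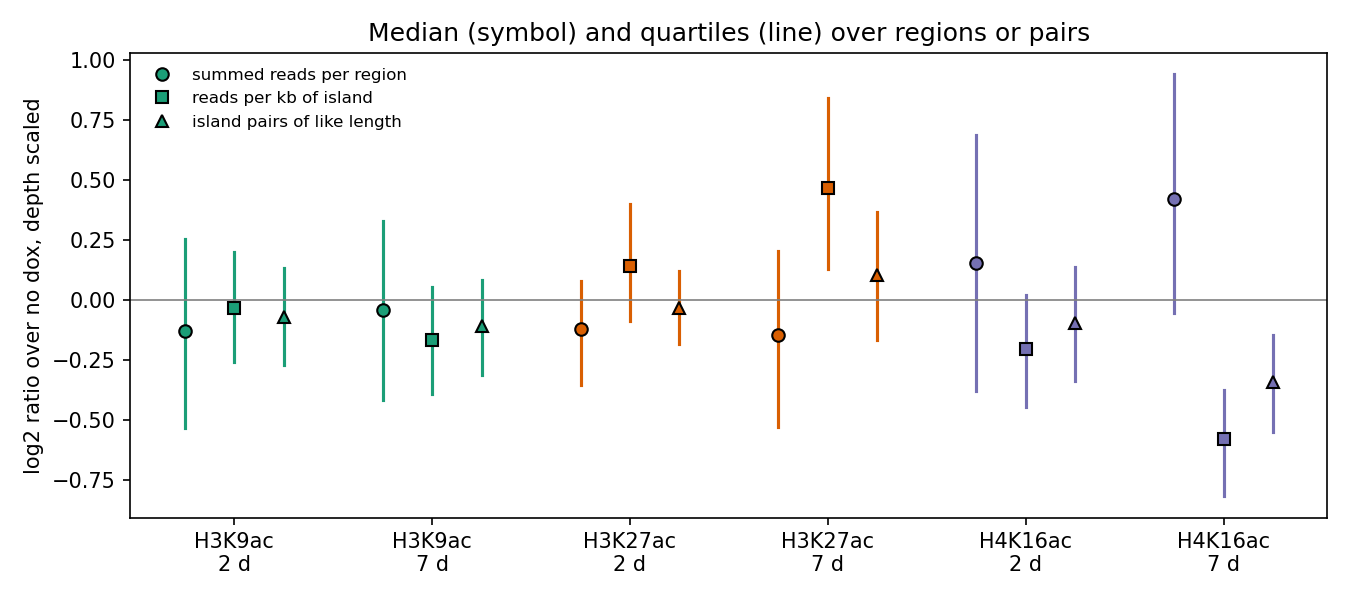
Depth-scaled log2 ratio over the library without doxycycline for each mark and time, as medians (symbols) and quartiles (lines) of summed reads per shared region, of reads per kb of island, and of island pairs of like length. At 7 days the sum and the 2 other measures lie on opposite sides of 0 for H3K27ac and H4K16ac.

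**Figure D3:**
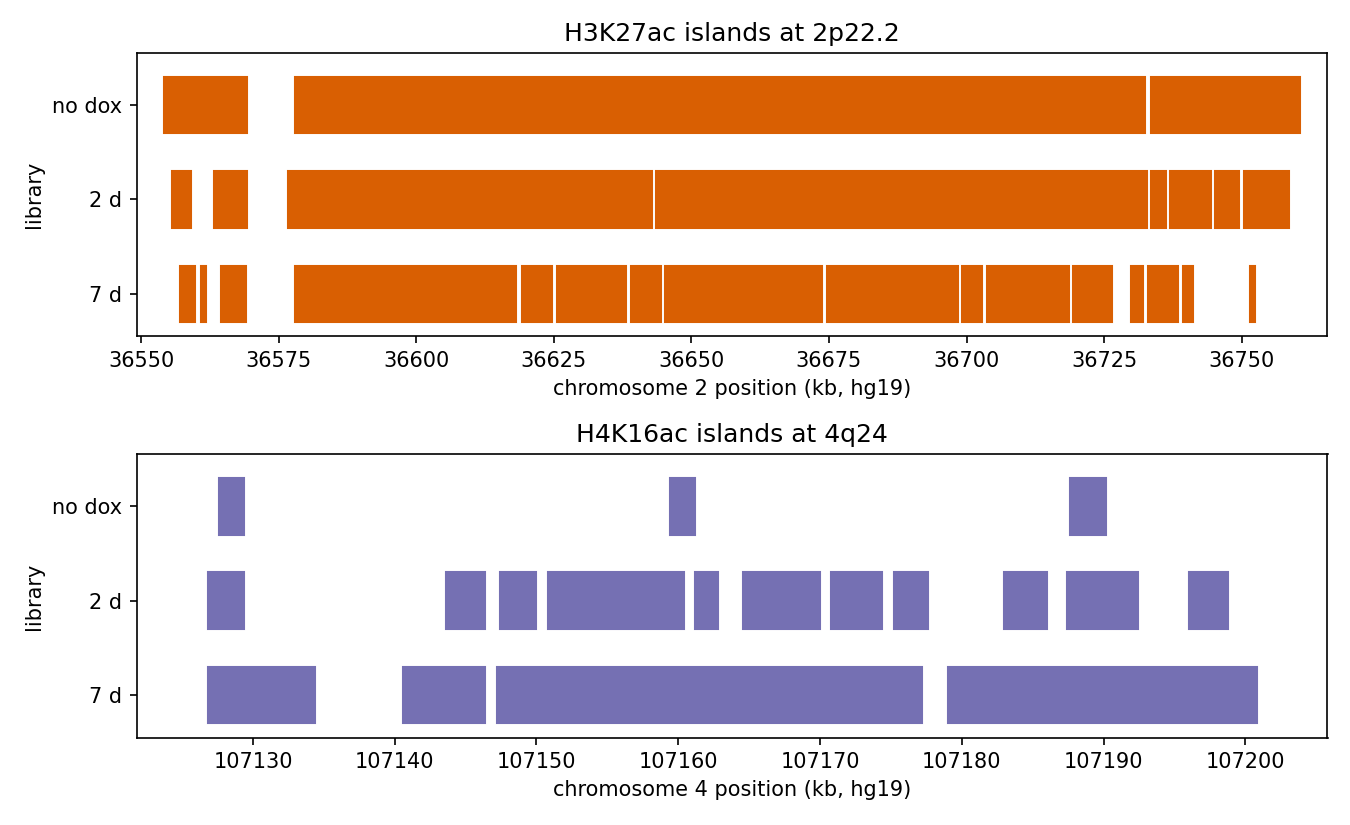
Islands as listed, drawn to scale on hg19, at the widest H3K27ac island without doxycycline (2p22.2) and at the region with the largest H4K16ac rise (4q24), with 1 row per library. The 154.4 kb H3K27ac island holds 10 islands at 7 days, and H4K16ac islands join into 1 of 30000 bp.

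The share of H4K16ac reads in islands shifted between chromosomes and bands, mostly with the length called there. The SD over bands of the log2 ratio of their share was 0.40 at 2 days and 0.28 at 7 days, against 0.15 and 0.15 for H3K9ac and 0.091 and 0.19 for H3K27ac, and the difference between marks was not tested. Chromosome 19, the most gene-dense chromosome, held 1.33% of H4K16ac reads without doxycycline (1.32 to 1.34), 0.670% at 2 days (0.664 to 0.677) and 1.05% at 7 days (1.04 to 1.05). Its covered length was 3.56, 2.28 and 6.34 Mb, or 1.29%, 0.683% and 1.08% of the list. The log2 ratios of this share were -0.99 and -0.34, against 0.10 and 0.023 for H3K9ac and -0.10 and 0.33 for H3K27ac. In regions with an island in all 3 lists the H4K16ac ratios were -0.51 and -0.22, and those of H3K27ac -0.086 and 0.32. Per kb of island the H3K27ac ratios of chromosome 19 were -0.033 and 0.0062, so its rise at 7 days went with its share of called length. That share was 2.60% without doxycycline and 3.25% at 7 days. The H3K27ac length called there fell, from 7.95 to 7.20 Mb, but less than in the list as a whole. The H4K16ac ratios of chromosome 19 per kb of island were -0.071 and -0.092, and those of the 23 chromosomes lay between -0.071 and 0.024 at 2 days and between -0.13 and 0.030 at 7 days. The gene-poor chromosomes 13 and 4 gained H4K16ac share at 2 days, by 0.37 and 0.29, and at 7 days, by 0.34 and 0.23. In regions with an island in all 3 lists these gains were 0.23 and 0.17, and 0.23 and 0.14. Chromosome X was at -0.38 and -0.32 and chromosome 21 at -0.15 and -0.0092. Chromosome X, with 0.414% of the reads without doxycycline, reversed in the regions of all 3 lists, to 0.091 and 0.095. The largest falls of single bands at 2 days were at 19p13.3 (-1.58), 11p15.5 (-1.46), 1p36.32 (-1.41), 9q34.2 (-1.28) and 1p36.33 (-1.22). The largest rises were at 4q32.2 (1.22), 13q21.32 (0.92), 4q28.3 (0.92), 13q21.31 (0.91) and 7p15.2 (0.90). In 19p13.3 H4K16ac islands covered 511 kb without doxycycline and 214 kb at 2 days, and in 4q28.3 they covered 563 and 1295 kb.

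The darkest Giemsa bands, which are gene-poor and replicate late, held 9.23% of H4K16ac reads without doxycycline (9.20 to 9.25), 12.01% at 2 days (11.98 to 12.04) and 11.4% at 7 days (11.41 to 11.44). Their share of the covered length rose with it, at 9.66%, 12.5% and 12.2%. Of the HRP control reads counted in each list's islands, 9.26%, 12.2% and 11.9% lay in these bands. The HRP library is the same for all lists, so these shares differ only through where islands were called. Of 69 such bands, 65 held a larger share at 2 days and 63 at 7 days. Giemsa-negative bands, which are gene-rich, went from 55.9% of reads to 52.2% and 53.3%. In H3K27ac the darkest bands held 7.38%, 7.80% and 6.67%, and in H3K9ac 8.65%, 8.20% and 8.80%. In regions with at least 50 H4K16ac reads in all 3 libraries, the median log2 ratio of summed reads in the darkest bands exceeded that in Giemsa-negative bands by 0.20 (0.15 to 0.27) at 2 days and 0.14 (0.10 to 0.19) at 7 days. Per kb of island the differences were 0.030 (0.0087 to 0.050) and -0.0077 (-0.027 to 0.011). In island pairs of like length they were 0.0995 (0.053 to 0.14) and 0.0088 (-0.028 to 0.058), so a difference above 0 was left at 2 days in both measures and at 7 days in neither. These intervals come from resampling bands 200 times and do not cover differences between libraries.

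**Figure D4:**
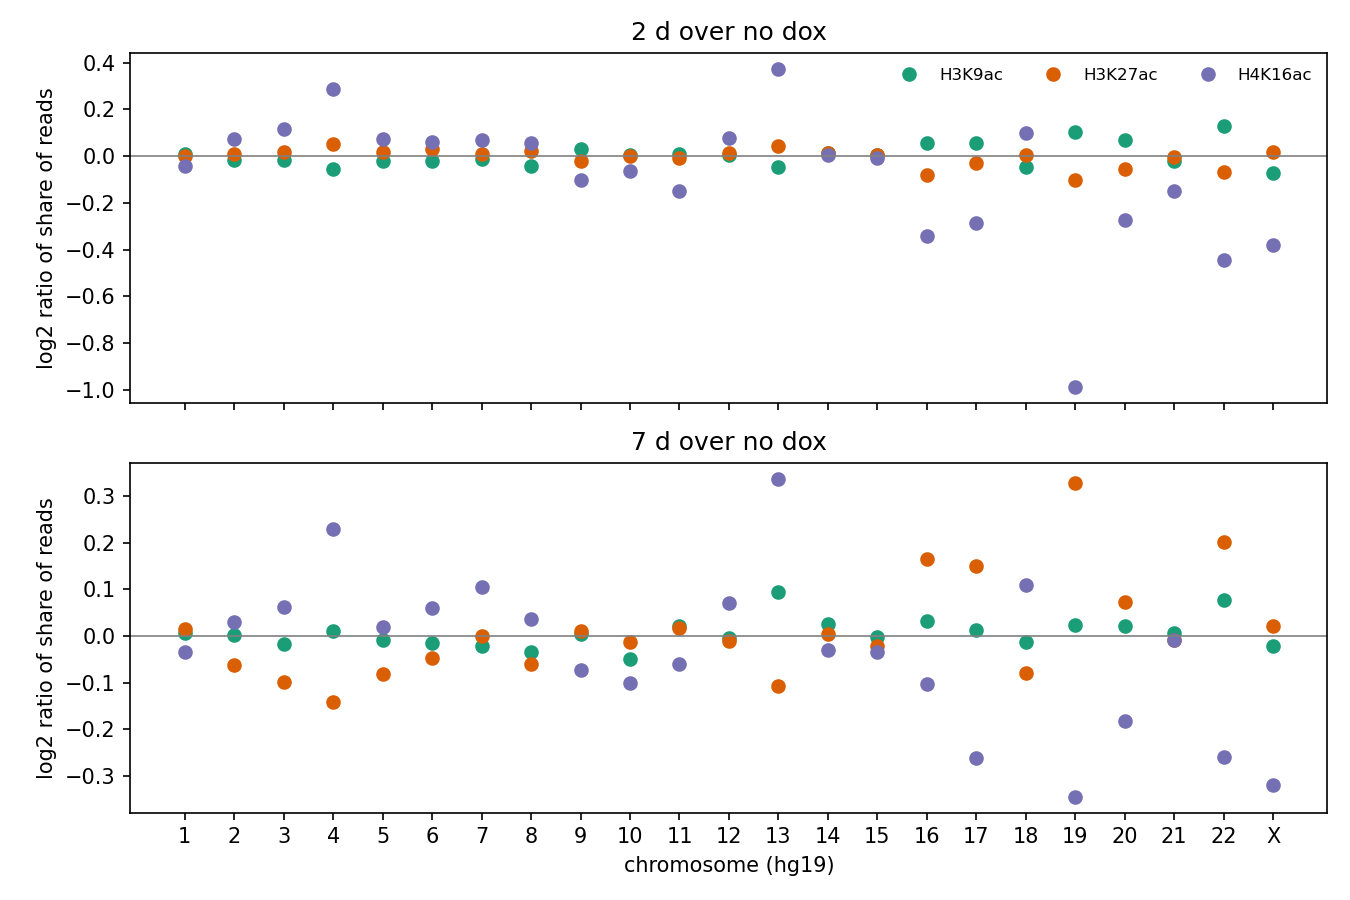
Log2 ratio of each chromosome's share of reads in islands at 2 days (upper) and 7 days (lower) over no doxycycline, with 1 point per mark and chromosome on hg19. The H4K16ac share of chromosome 19 is at -0.99 and -0.34, and that of H3K27ac at 7 days at 0.33. Per kb of island these values are -0.071, -0.092 and 0.0062.

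The 2 times were compared over regions present in all 3 lists of a mark, where both ratios share the library without doxycycline. Across regions, which are not independent replicates, Spearman's correlation was 0.52 for H3K9ac (45695 regions), 0.11 for H3K27ac (36490) and 0.64 for H4K16ac (34852). Unchanged Poisson counts against the same shared library gave 0.57, 0.32 and 0.61. The covariance exceeded the simulated one by 0.20, 0.024 and 0.41. With at least 50 reads in all 3 libraries the H3K27ac correlation was 0.015, against 0.33 simulated, and its excess covariance 0.00085. Part or all of any excess may come from island edges and from the shared library, which cannot be split.

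Measured ratios of different marks at overlapping regions were nearly uncorrelated. Counting error and island edges in single libraries lower such correlations, so changes shared between marks are not excluded. Over 16725 to 29395 region pairs, Spearman's correlation was -0.031 and 0.089 between H3K9ac and H3K27ac at 2 and 7 days. It was -0.014 and 0.051 between H3K9ac and H4K16ac, and 0.089 and -0.10 between H3K27ac and H4K16ac. Per kb of island the 6 values lay between -0.0024 and 0.029. Islands of H3K27ac overlapped H3K9ac islands in 76.0% without doxycycline, 76.4% at 2 days and 61.2% at 7 days. Islands of H4K16ac overlapped H3K27ac in 38.3%, 36.7% and 44.7%, against 14.8%, 15.0% and 21.0% for random placement. H4K16ac regions with an H3K27ac island without doxycycline had a median ratio of 0.078 at 2 days and 0.37 at 7 days, and those without one 0.25 and 0.48. Per kb the medians were -0.21 and -0.58 with, and -0.20 and -0.58 without.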

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

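The test of copy number, the comparisons of bands and chromosomes per kb of island and of island pairs of like length, and the choice of bands, chromosome 19 and wide islands as measures came after the data were seen. The differences between marks given here were not tested, because each mark and time has 1 library.

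Covered length moved in opposite directions in H3K27ac and H4K16ac. It was 0.839 times that without doxycycline in H3K27ac and 1.21 times in H4K16ac at 2 days, and 0.724 and 2.12 times at 7 days. The size depends on the filter: at 7 days it was 1.46 in H4K16ac and 0.759 in H3K27ac with a fold of at least 2, and 5.49 and 0.410 with at least 50 reads, a minimum that removes more of a shallow list. Thinning the 7-day H4K16ac counts to the depth without doxycycline left a ratio of 1.99, below the bound of 2 set for excluding depth, and the island edges still came from the deeper library. Depth and a wider spread of H4K16ac cannot be told apart here, as the 7-day library had 3.11 times the size, and an effect of IDH1-R132H stays open and untested.

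The share of H4K16ac reads in the darkest Giemsa bands rose by 2.20 percentage points at 7 days, and that of H3K27ac changed by -0.714. In regions shared by all 3 lists the H4K16ac share went from 8.19% to 9.37%. In regions with 50 reads in all 3 lists the darkest bands exceeded the Giemsa-negative ones by 0.143 in log2 ratio at 7 days, and by 0.143 within classes of read density, which had been set to exclude island calling and uniform background. That bound was wrong, because region sums move with called length: at 7 days the difference was -0.0077 per kb and 0.0088 in pairs of like length, so island calling and background reads may account for it there. At 2 days 0.030 per kb and 0.0995 (0.053 to 0.14) in pairs were left of 0.20, and these values do not clear the bound set. Over the whole list the darkest bands held 9.23% without doxycycline and 12.01% at 2 days of reads, and 9.66% and 12.5% of called length. Called length as the whole cause is thus not excluded at that time. Of the HRP control reads in islands these bands held 9.26% and 12.2%, which reflects only where islands were called in 1 shared control library. To exclude a change in copy number, the bound set needed both other marks far below H4K16ac. H3K9ac argues against such a change: its 2-day differences of -0.096 in sums, -0.021 per kb and -0.030 in pairs had intervals below those of H4K16ac. H3K27ac was at 0.0821, 0.038 and 0.055, which is no smaller than H4K16ac per kb. The bound was thus met in sums but not per kb or in pairs, and copy number is not excluded. GC bias and an effect of induction stay open, untested.

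Islands of H3K27ac of 20 kb or more fell from 1323 to 154 at 7 days in a library with 0.375 times the size. Reads in these regions changed by -0.048 (-0.071 to -0.024) in log2 ratio relative to other shared regions, an interval that spans the bound of -0.05 for fragmentation of islands at lower depth and lies far above the bound of -0.20 set for excluding it. At 2 days the difference was 0.029. Wide islands were split in deeper libraries too, in 79.3% for H3K9ac at 2 days against 77.7% for H3K27ac, so splitting of islands chosen by width was not limited to lower depth. These sums leave out reads in the gaps between islands and move with called length. In them a loss as large as that bound was not seen, and fragmentation and a smaller loss cannot be told apart.

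On chromosome 19 the log2 ratio of the share of reads at 2 days was 0.10 in H3K9ac, -0.10 in H3K27ac and -0.99 in H4K16ac, and at 7 days 0.023, 0.33 and -0.34. In regions with an island in all 3 lists the H4K16ac values were -0.51 and -0.22, and per kb of island -0.071 and -0.092. The H3K27ac values per kb of island were -0.033 and 0.0062, so its rise at 7 days went with its share of called length. The H3K27ac length called there fell, from 7.95 to 7.20 Mb, but less than in the list as a whole.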

How the results depend on the processing

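The thinned counts, island pairs of like length, joined islands, and all settings for the bands and chromosome 19 were chosen after seeing the data. Of the values that answer a comparison, 87 stayed within their 95% interval or, for counts and covered lengths, within 1.5 times the value reported (for correlations, within an approximate 95% range that takes regions as independent), 113 moved and 10 reversed; of the named regions under other settings, 69 stayed, 22 moved and 17 reversed. The cause was not tested for any of them, except that summed reads depend on called length. The planned settings for promoters and gene lists were not run, and centring on the median gives a median of 0 by construction. No paired analysis was possible because each mark and time has 1 library. Depth limits the shallow libraries: the minimum of 50 reads left 23985 of 84641 H3K27ac islands at 7 days and 21664 of 110234 H4K16ac islands without doxycycline.

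With at least 50 antibody reads, islands numbered 41036 and 55833 for H3K9ac without doxycycline and at 2 days, 23985 for H3K27ac at 7 days, and 21664 and 39395 for H4K16ac without doxycycline and at 2 days. Covered length was 122 Mb for H3K27ac at 7 days, and 107 and 214 Mb for H4K16ac without doxycycline and at 2 days. Over the length without doxycycline it was 0.410 times for H3K27ac at 7 days, and 2.01 and 5.49 times for H4K16ac at 2 and 7 days. The median fold over HRP was 3.05, 3.01 and 2.71 for H3K9ac at the 3 times, 5.51 and 8.44 for H3K27ac at 2 and 7 days, and 3.01 and 2.69 for H4K16ac without doxycycline and at 2 days. With a fold of at least 2, H4K16ac at 7 days had 49251 islands over 317 Mb. Joined across gaps of at most 2 kb, islands of 20 kb or more numbered 1375, 1696 and 2578 for H3K9ac, 2680, 1728 and 869 for H3K27ac, and 891, 2278 and 7951 for H4K16ac.

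Overlaps are given in the order of islands without doxycycline against 2 and 7 days, then of 2-day and 7-day islands against none. Requiring 50% of the island gave 57.6%, 62.9%, 52.2% and 52.0% for H3K9ac, 75.8%, 53.7%, 83.5% and 61.4% for H3K27ac, and 45.2%, 69.5%, 37.4% and 27.2% for H4K16ac. An FDR of at most 0.001 gave 72.4%, 73.0%, 61.8% and 64.8% for H3K9ac, and 53.8%, 73.4%, 57.3% and 60.1% for H4K16ac. For H3K27ac it gave 87.7% and 78.8% for islands without doxycycline and 65.5% for 7-day islands. The same number of islands per list gave 65.6%, 71.1%, 66.5% and 67.7% for H3K9ac, 81.6%, 60.4%, 90.1% and 73.8% for H3K27ac, and 56.8%, 77.2%, 52.8% and 54.7% for H4K16ac.

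Median log2 ratios at 2 and 7 days, scaled by reads in islands, were -0.14 and -0.10 for H3K9ac, -0.018 and -0.12 for H3K27ac, and 0.083 and -0.089 for H4K16ac. Reads per kb gave -0.032 and -0.17, 0.14 and 0.46, and -0.20 and -0.58 in the same order of marks. Island pairs of like length gave -0.071 and -0.11, -0.034 and 0.11, and -0.098 and -0.34. Regions of at most 20 kb gave -0.13 for H3K9ac at 2 days, and 0.13 and 0.39 for H4K16ac. At least 50 reads in both libraries gave -0.10 for H3K9ac at 7 days, -0.090 and -0.058 for H3K27ac, and 0.059 and 0.25 for H4K16ac.

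Per kb of island, 17 of the named regions reversed. Only stretches that passed the caller are counted, so a reversal does not show that the signal was unchanged. For H3K9ac at 2 days 1q42.13, 2q33.1 and 15q21.3 were at 0.89, 1.71 and -0.13, and at 7 days 8p22, 3q26.32 and 3p21.31 at 0.66, 0.24 and -0.077. For H3K27ac at 2 days 6p21.1, 22q11.23, 14q24.2 and 6q25.3 were at 0.89, 1.61, 0.18 and -1.68, and at 7 days 3p22.3 and 8p11.22 at 0.64 and 2.04. For H4K16ac at 2 days 1p36.12, 22q13.31 and 18q21.2 were at 0.80, 0.25 and -0.75, and at 7 days 18q12.1 and 9p22.3 at -0.21 and -0.76.

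The share of reads in the darkest bands at an FDR of at most 0.001 was 8.48%, 7.996% and 8.63% for H3K9ac at the 3 times, 7.78% and 6.60% for H3K27ac at 2 and 7 days, and 8.97%, 11.8% and 11.2% for H4K16ac. In regions shared by all 3 lists it was 7.55%, 7.08% and 7.36%, 7.18%, 7.51% and 6.31%, and 8.19%, 9.68% and 9.37% for the 3 marks. There the share on chromosome 19 was 1.66%, 1.72% and 1.70% for H3K9ac, 2.99%, 2.82% and 3.73% for H3K27ac, and 0.911%, 0.640% and 0.784% for H4K16ac.

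With 50 reads in all 3 libraries the H3K27ac correlation of the 2-day and 7-day ratios was 0.015. Per kb, correlations between marks at 2 and 7 days were -0.0024 and 0.023 for H3K9ac with H3K27ac, 0.0064 and 0.019 for H3K9ac with H4K16ac, and 0.024 and 0.029 for H3K27ac with H4K16ac.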

Other observations

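The presence or absence of an island over the 3 times, its relation to H3K27ac, and the bands were examined after the data were seen. Of 83389 merged H3K27ac regions, 36490 had an island in all 3 lists and held 93.5% of the reads without doxycycline. The regions in all 3 lists were 45695 of 124890 for H3K9ac, with 80.2% of the reads, and 34852 of 116521 for H4K16ac, with 70.6%. Regions with islands at both doxycycline times and none without numbered 12303 for H3K9ac, 2278 for H3K27ac and 11557 for H4K16ac. Those with an island in 1 list only numbered 13253, 3584 and 21358 without doxycycline, 21867, 5445 and 12964 at 2 days, and 17014, 26894 and 17662 at 7 days, in the same order of marks. H3K9ac and H4K16ac regions with no H3K27ac island before doxycycline were more often present in 1 list of a pair only, in both directions, in a contrast that was not matched on reads. For H3K9ac they were missing at 2 and 7 days in 48.0% and 49.4%, against 13.0% and 14.2% of those with one, and new in 62.4% and 59.2%, against 17.6% and 15.99%. For H4K16ac they were missing in 55.7% and 44.5%, against 35.2% and 25.2%, and new in 49.5% and 48.0%, against 24.2% and 25.4%.

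The H3K27ac shift at 7 days away from the darkest Giemsa bands was smaller but present per kb of island. The darkest bands differed from the Giemsa-negative ones by -0.20 (-0.23 to -0.15) in summed reads, -0.093 (-0.13 to -0.063) per kb, and -0.13 (-0.19 to -0.075) in island pairs of like length. Within classes of read density it was -0.20 (-0.23 to -0.14). At 2 days the differences in sums, per kb and in pairs were 0.082, 0.038 and 0.055, in the opposite direction. The 7-day library had 0.375 times the size of that without doxycycline, and GC bias was not checked. Island calling in a smaller library, GC bias and an effect of induction were not tested and stay open for this shift.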
